A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

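Total RNA of 3 haploid Saccharomyces cerevisiae strains was measured on 6 arrays with 2 colours. The strains were BY4742, called parental here, and its derivatives lacking ERG6 or SNQ2. BY4742 is a laboratory strain of mating type alpha that carries his3, leu2, lys2 and ura3 mutations. Each array set cDNA from cells treated with compound 089 at 0.2 mM for 4 h in rich medium, labelled with Cy5, against cDNA from untreated cells of the same strain, labelled with Cy3, per the labels. Each strain had 2 arrays, which the series text calls biological replicates. The treated cells carried Cy5 on all 6 arrays, so that a dye effect specific to a gene stays in each strain's response. It cancels in a difference between strains only where its size is equal in both.

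The authors deposited 1 signed value per feature and array for 7045 features, with 0 missing values and 1 row per feature. The slides were read on a GenePix 4000B scanner, per the labels. Background correction, normalization within arrays, spot filters, log base and direction are not given in the sources used here. The values were taken as the log2 ratio of treated over untreated, because the sample titles in the labels name treated against untreated and the treated RNA is in channel 1. This direction is likely but not stated, and if it were the opposite every sign printed here would turn. The largest value was 5.52, a ratio that a log10 scale would put beyond the range of a 16-bit scanner, while a natural log was not excluded and would make each fold larger than given. The medians of the deposited log2 values over all features were 0.011 and 0.0054 on the parental arrays, -0.046 and -0.055 on the erg6 deletion arrays, and -0.0029 and -0.010 on the snq2 deletion arrays. They lie near 0, and whether a centring step was applied is not stated in the sources used here. Signal over background could not be computed from these values, and the number of arrays limits the precision.

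Features named Blank (144) or empty (539) were kept out of the gene tests and used as control spots, leaving 6362 genes. Of these, 5826 matched a locus tag of the RefSeq gene table of assembly R64, which was used for names alone. The other 536 did not match, are called not annotated here and keep the name of the file. Symbols and synonyms served only to find list members and genes named in advance. Probe sequences and spot positions were not analysed here, so cross-hybridisation between paralogs or overlapping frames stays open, and no coordinates are given.

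In limma 3.58.1 (R 4.3.3), lmFit fitted 1 mean per strain to all 6 arrays and eBayes moderated the variance, with 3 residual and 2.45 prior degrees of freedom. P-values were adjusted by Benjamini-Hochberg over the 6362 genes in each of 6 contrasts, and the threshold was an adjusted p of 0.05. The contrasts were each strain's mean against 0, the mean over the 3 strains against 0, and each deletion strain's response minus the parental response. Control spots were tested with the variance prior of the genes at the largest unadjusted p that passed among genes. Values after ± are standard errors of the fit, with n = 2 arrays per strain. With 2 arrays per strain, a p-value rests on the spread of each gene pooled over all 3 strains and taken as equal in them. Replicates differed more in the erg6 deletion strain, as given below, so its standard errors and p-values can be too small.

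The 34 gene lists were written before the data were examined and cover drug efflux, ergosterol synthesis, nitrogen, sulfur and amino acid metabolism, carbon metabolism and respiration, stress responses and protein quality control, the cell wall, proteases and autophagy, ribosomes and their assembly, phosphate, iron and polyamines, histones and replication, mating, cell type and meiosis markers, and stationary phase. Each was tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 34 lists in a contrast, and again with an estimated correlation. The fry test, which asks whether a list moves one way on balance and compares it with no other genes, was an alternative. Lists overlap, so their tests are not independent. Counts of members are given over all genes tested and adjusted over the list alone.

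Named genes followed a rule set before the data were examined: in each contrast the 10 highest and 10 lowest values among genes past the threshold with both replicates on one side, up to 4 members per described list with the smallest p, and ERG6, SNQ2, PDR5, YOR1, PDR3, HIS3, LEU2, LYS2 and URA3. Genes chosen after their values were seen are said to be so. Correlations between strains are across genes, which are not independent replicates, and carry no p.

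Alternatives set before the data were examined were median-centred, equally scaled and quantile-normalised arrays, the replicate number as a block, each array left out in turn, a fit to the compared strains alone, robust eBayes, array weights, a 1.5-fold minimum, an estimated correlation and fry. Added after seeing the data were a requirement to lie outside the central 95% of the control spots, annotated genes only, and removal of genes at or below -3 on either erg6 deletion array. The fits were tested on simulated data with the moderated spread of each gene, taken as equal in all strains. Genes were drawn independently and without spot effects. In the real data the difference of replicates had an SD across genes of 0.675 in the erg6 deletion, 0.357 in the parental and 0.332 in the snq2 deletion strain. With 50 genes changed at each size among 6362 in the erg6 deletion arrays, 22% were recovered at a log2 change of 0.5, 90% at 1, 96% at 2 and 100% at 3, with 7 false calls. For the erg6 deletion minus parental difference the shares were 0%, 76%, 92% and 98%, with 8 false calls. In the parental contrast, camera found 3 of 3 lists shifted by 0.5 and 0 of 31 others. The simulated genes were independent, so this does not bear on lists of correlated genes. The shares and false calls are not error rates of the real data.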

Results

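The response of yeast to compound 089, whose chemistry is not given in the sources used here, was measured on 6 arrays in 3 strains with 2 biological replicates each. One strain was the parental BY4742. Another lacked ERG6, the sterol C-24 methyltransferase of late ergosterol synthesis, and the other lacked SNQ2, an ABC transporter of the plasma membrane that exports drugs. Each array compared cells treated with 0.2 mM 089 for 4 h with untreated cells of the same strain. The comparisons are the response in each strain, the mean response, and how the response of each deletion strain differed from that of the parental strain, which the series text names as the reference. All values are log2 ratios of treated over untreated, with this direction and the base 2 taken as likely and not stated by the sources used here. In the opposite direction every sign would turn. Replicates correlated across genes at r = 0.901 in the parental, 0.713 in the erg6 deletion and 0.916 in the snq2 deletion strain.

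ERG6 and SNQ2 themselves were not decisive as a check of the labels, because both channels of an array held the same strain and a ratio at a deleted locus compares background with background. ERG6 had a ratio of -0.75 ± 0.11 (SE, n = 2) on the erg6 deletion arrays, where the gene is absent, and -0.55 ± 0.11 in the parental strain, a call lost without parental replicate 1 (adjusted p = 0.110, over a range of 0.00410 to 0.110). SNQ2 had 0.12 ± 0.09 on the snq2 deletion arrays, which did not pass, and -0.35 ± 0.09 in the parental strain, a call lost without parental replicate 1 (adjusted p = 0.136) or 2 (adjusted p = 0.148, over a range of 0.00993 to 0.148). Over LEU2, LYS2 and URA3 in 3 strains and the deleted gene in each deletion strain, 6 of 11 tests at loci named as mutated or deleted passed the threshold. HIS3, whose usual allele in this background lacks only part of the gene, is not among the 11, and it had -1.19 ± 0.18 in the snq2 deletion strain and did not pass in the parental (0.21 ± 0.18) and erg6 deletion strains (-0.18 ± 0.18). The largest of the 6 was LEU2 at -2.37 ± 0.65 in the snq2 deletion strain, with replicates at -1.22 and -3.51, which did not pass without replicate 2 (adjusted p = 0.267), with the replicate block (0.0504) or with robust eBayes (0.0557), over a range of 0.00265 to 0.267. LYS2 passed at 0.36 ± 0.10 in the parental, -0.50 ± 0.10 in the erg6 deletion and 0.45 ± 0.10 in the snq2 deletion strain. The parental LYS2 call was lost without parental replicate 1 or 2 (adjusted p = 0.273 and 0.0953), without either snq2 deletion array (0.0589 each), with quantile normalisation (0.0536) and with the replicate block (0.0507), over a range of 0.0157 to 0.273. The erg6 deletion call was lost without replicate 2 of that strain (0.0729) and in a fit to it alone (0.0690), over a range of 0.00884 to 0.0729, and the snq2 deletion call without replicate 1 or 2 of that strain (0.0737 and 0.145), over a range of 0.00897 to 0.145. These loci and the control spots passed the test often, so a call alone does not show that a transcript changed. The central 95% of the 683 control spots spanned -1.36 to 2.49 in the parental, -1.87 to 3.57 in the erg6 deletion and -1.43 to 2.00 in the snq2 deletion response. Empty spots had medians of 0.70, 2.11 and 0.55 in these responses, and the limits are not symmetric about 0. The numbers of genes above and below them therefore do not compare rises with falls.

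**Figure D1:**
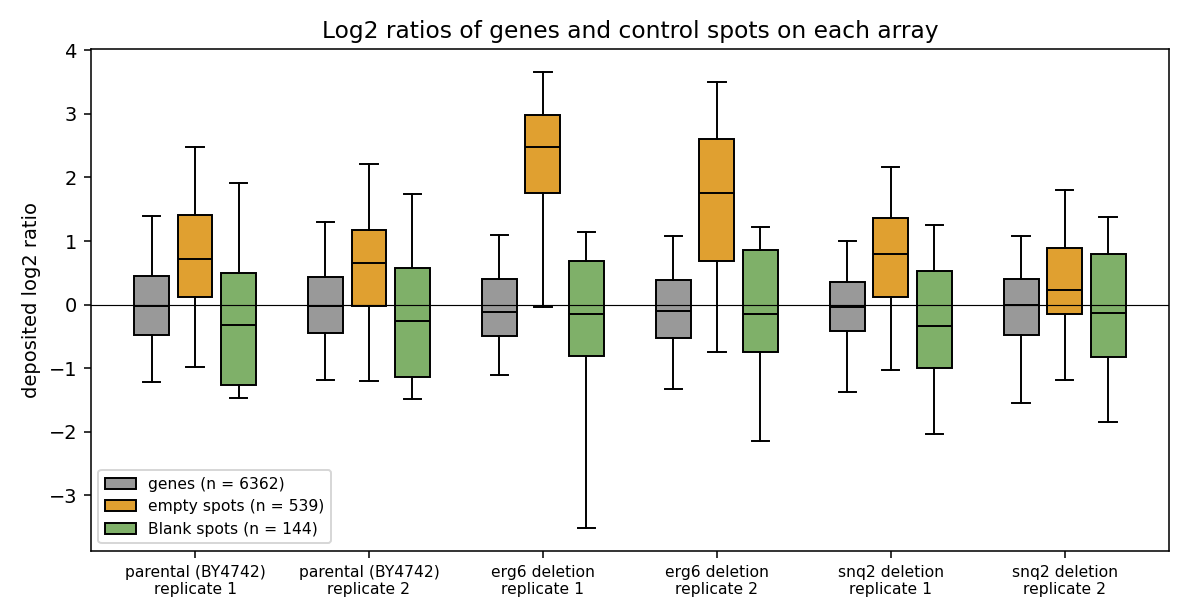
Deposited log2 ratios (vertical axis) of genes, empty spots and Blank spots on each of the 6 arrays (horizontal axis). Boxes span the quartiles with the median as a line, and whiskers reach from the 5th to the 95th percentile. Medians of genes lie between -0.11 and -0.012, while medians of empty spots reach 2.47 and 1.76 on the erg6 deletion arrays.

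In the parental strain, nuclear genes of respiration, protein folding, the cell wall and stress defence fell under 089. Of the nuclear genes of the respiratory chain, 24 of the 33 fell, 3 rose and 6 did not pass, as when adjusted over the list alone. Their median was -0.68 (camera adjusted p = 8.99e-05, adjusted p = 0.343 with an estimated correlation). ATP2, the beta subunit of the F1 ATP synthase, fell by 2.32 ± 0.09 and RIP1, the Rieske protein of complex III, by 1.88 ± 0.08. ATP14 of the ATP synthase fell by 1.68 ± 0.08, whereas QCR10, a small subunit of complex III, rose by 2.08 ± 0.09. HAP4, the activating subunit of the factor that drives respiratory genes, was among the 10 lowest genes at -2.18 ± 0.13.

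Of the heat shock and chaperone genes, 20 of the 26 fell, 3 rose and 3 did not pass, as when adjusted over the list alone. Their median was -0.69 (camera adjusted p = 8.99e-05, adjusted p = 0.343 with an estimated correlation). STI1, a co-chaperone of Hsp90, fell by 2.25 ± 0.10, and HSP60, the mitochondrial chaperonin, by 1.16 ± 0.09. Of the cell wall genes, 21 of the 36 fell, 3 rose and 12 did not pass, as when adjusted over the list alone. Their median was -0.65 (camera adjusted p = 5.00e-04, adjusted p = 0.343 with an estimated correlation). The wall proteins PIR3, SED1 and HSP150 fell by 2.09 ± 0.11, 1.92 ± 0.11 and 1.80 ± 0.12, and the aspartyl protease YPS1 by 2.16 ± 0.14. Of the general stress genes under Msn2 and Msn4, 18 of the 31 fell, 4 rose and 9 did not pass (19 and 5 when adjusted over the list alone). Their median was -0.67 (camera adjusted p = 0.00492, adjusted p = 0.644 with an estimated correlation). PNC1, a nicotinamidase, fell by 1.85 ± 0.08, GLO1, glyoxalase I, by 1.98 ± 0.13, DDR2 by 1.74 ± 0.10 and the polyubiquitin gene UBI4 by 1.38 ± 0.09.

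Of the trehalose and glycogen genes, 11 of the 18 fell, 1 rose and 6 did not pass, as when adjusted over the list alone. Their median was -0.63 (camera adjusted p = 0.0113, adjusted p = 0.640 with an estimated correlation). TSL1 and TPS3 of the trehalose synthase complex fell by 0.91 ± 0.11 and 0.96 ± 0.09, while GSY2, a glycogen synthase, rose by 1.65 ± 0.15. Of the glyoxylate cycle and gluconeogenesis genes, 12 of the 21 fell, 2 rose and 7 did not pass, as when adjusted over the list alone. Their median was -0.43 (camera adjusted p = 0.0173, adjusted p = 0.640 with an estimated correlation), with the isocitrate dehydrogenase gene IDP2 at -1.59 ± 0.10 and the malate synthase gene MLS1 at -1.23 ± 0.11. The cytosolic ribosomal proteins were the list past the threshold that moved upward, and 63 of the 136 rose, 26 fell and 47 did not pass (64 and 27 when adjusted over the list alone). Their median was 0.25 (camera adjusted p = 0.0300, adjusted p = 0.644 with an estimated correlation). RPL31A and RPL25 rose by 1.68 ± 0.11 and 1.52 ± 0.09, while RPS11A fell by 2.00 ± 0.12. Without parental replicate 1 the adjusted p of this list was 0.0956, and over all alternatives other than the estimated correlation it ranged from 0.00665 to 0.0956.

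Of the 10 highest ratios of the parental strain, 7 were at mitochondrially encoded features. ATP8 and ATP6, ATP synthase subunits, had 4.71 ± 0.13 and 3.97 ± 0.20, COX1, a cytochrome oxidase subunit, had 4.01 ± 0.17, and its intron frame AI5_ALPHA had 3.94 ± 0.11. SKI3, a cofactor of the cytoplasmic exosome, rose by 3.62 ± 0.18. The lowest ratios included VPS30, a subunit of phosphatidylinositol 3-kinase complexes, at -3.48 ± 0.11, ERG9, squalene synthase, at -2.89 ± 0.11, the eisosome gene NCE102 at -2.47 ± 0.09 and the iron-sulfur scaffold gene ISU1 at -2.29 ± 0.09. In all, 3434 of 6362 genes passed, 1736 higher and 1698 lower, and 983 of these changed at least 2-fold. In the same contrast 36.0% of the 539 empty and 70.1% of the 144 Blank spots passed, and 240 (56 higher, 184 lower) of the genes that passed lay outside the control range. The count was 1914 without parental replicate 1 and 2149 without replicate 2.

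In the erg6 deletion strain, ribosomal protein genes and nuclear genes of respiration and the carbon cycles rose under 089, while chaperone genes fell. Of the cytosolic ribosomal proteins, 109 of the 136 rose, 3 fell and 24 did not pass (112 and 3 when adjusted over the list alone). Their median was 1.03 (camera adjusted p = 3.30e-24, adjusted p = 0.187 with an estimated correlation). RPL3 and RPL40B rose by 1.77 ± 0.09 and 1.70 ± 0.08, and RPL12B by 1.81 ± 0.13. Of the respiratory chain genes, 26 of the 33 rose, 2 fell and 5 did not pass, as when adjusted over the list alone. Their median was 0.97 (camera adjusted p = 1.23e-08, adjusted p = 0.187 with an estimated correlation), with the cytochrome oxidase gene COX7 at 1.72 ± 0.08 and the ATP synthase gene ATP7 at 1.35 ± 0.08. Of the tricarboxylic acid cycle genes, 16 of the 20 rose, 2 fell and 2 did not pass, as when adjusted over the list alone. Their median was 0.96 (camera adjusted p = 1.24e-05, adjusted p = 0.193 with an estimated correlation). The succinate dehydrogenase gene SDH3 rose by 1.70 ± 0.09 and the fumarase gene FUM1 by 1.40 ± 0.09.

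Of the glyoxylate cycle and gluconeogenesis genes, 17 of the 21 rose, 2 fell and 2 did not pass, as when adjusted over the list alone. Their median was 1.02 (camera adjusted p = 9.90e-06, adjusted p = 0.193 with an estimated correlation). FBP1 and PCK1, enzymes specific to gluconeogenesis, rose by 1.47 ± 0.10 and 1.27 ± 0.09. Of the glycolysis and fermentation genes, 14 of the 21 rose, 3 fell and 4 did not pass (15 and 3 when adjusted over the list alone). Their median was 0.69 (camera adjusted p = 0.00188, adjusted p = 0.377 with an estimated correlation), with GPM1 at 1.26 ± 0.09 and FBA1 at 1.12 ± 0.09. Of the hexose transporter genes, 10 of the 14 fell, 2 rose and 2 did not pass, as when adjusted over the list alone. Their median was -0.60 (camera adjusted p = 0.0222, adjusted p = 0.231 with an estimated correlation). HXT1, HXT3, HXT6 and HXT7 fell by 1.36 ± 0.13, 1.23 ± 0.11, 1.06 ± 0.09 and 1.21 ± 0.12. Of the ammonium assimilation and export genes, 8 of the 11 rose, 2 fell and 1 did not pass, as when adjusted over the list alone. Their median was 0.38 (camera adjusted p = 0.0190, adjusted p = 0.231 with an estimated correlation). ADY2, an acetate transporter also linked to ammonium export, rose by 1.80 ± 0.11, and the glutamate dehydrogenase genes GDH2 and GDH3 by 1.24 ± 0.10 and 1.01 ± 0.11.

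Of the heat shock and chaperone genes, 21 of the 26 fell, 1 rose and 4 did not pass (22 and 1 when adjusted over the list alone). Their median was -0.75 (camera adjusted p = 2.20e-05, adjusted p = 0.187 with an estimated correlation). The Hsp70 gene SSA4 fell by 1.65 ± 0.10 and YDJ1, an Hsp40 co-chaperone, by 1.58 ± 0.10. Of the general stress genes, 19 of the 31 rose, 2 fell and 10 did not pass, as when adjusted over the list alone. Their median was 0.60 (camera adjusted p = 8.64e-05, adjusted p = 0.367 with an estimated correlation), with RTN2 at 1.49 ± 0.09 and the mitochondrial superoxide dismutase gene SOD2 at 1.32 ± 0.08. Of the stationary phase genes, 14 of the 21 rose, 1 fell and 6 did not pass (14 and 2 when adjusted over the list alone). Their median was 0.57 (camera adjusted p = 0.00110, adjusted p = 0.271 with an estimated correlation). Of the proteasome genes, 21 of the 34 rose, 5 fell and 8 did not pass (22 and 5 when adjusted over the list alone). Their median was 0.47 (camera adjusted p = 5.47e-04, adjusted p = 0.187 with an estimated correlation), with RPT3 at 1.44 ± 0.12 and RPT1 at 1.38 ± 0.11. Of the vacuolar and secreted protease genes, 11 of the 17 rose, 1 fell and 5 did not pass, as when adjusted over the list alone. Their median was 0.72 (camera adjusted p = 0.00232, adjusted p = 0.193 with an estimated correlation). PRB1 and PEP4, the vacuolar proteases B and A, rose by 1.20 ± 0.08 and 0.93 ± 0.09, and PBI2, an inhibitor of protease B, by 1.41 ± 0.09.

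Of the oxidative stress and glutathione genes, 15 of the 33 rose, 9 fell and 9 did not pass, as when adjusted over the list alone. Their median was 0.39 (camera adjusted p = 0.0191, adjusted p = 0.224 with an estimated correlation), with the thioredoxin gene TRX1 at 1.51 ± 0.10. Of the cell wall genes, 15 of the 36 rose, 6 fell and 15 did not pass (16 and 6 when adjusted over the list alone). Their median was 0.21 (camera adjusted p = 0.0334, adjusted p = 0.271 with an estimated correlation). That call was lost without replicate 1 (median 0.37, adjusted p = 0.0625) and without replicate 2 (median 0.22, adjusted p = 0.0689) of this strain, over a range of 0.00698 to 0.0689. Of the hypoxic and seripauperin genes, 9 of the 21 rose, 4 fell and 8 did not pass, as when adjusted over the list alone. Their median was 0.41 (camera adjusted p = 0.0410, adjusted p = 0.499 with an estimated correlation), with OLE1, the fatty acid desaturase gene, at 1.45 ± 0.16. The call of the hypoxic list was lost without replicate 1 of this strain (adjusted p = 0.114), with centred arrays (adjusted p = 0.0536), annotated genes only (0.0555) and without genes at the floor of the erg6 deletion arrays (0.0524), over a range of 0.0262 to 0.114.

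Among the highest ratios in this strain were SOL4, a 6-phosphogluconolactonase gene, at 5.12 ± 0.86, ALE1, a lysophospholipid acyltransferase gene, at 4.00 ± 0.23, YRR1, a regulator of drug resistance genes, at 3.09 ± 0.13, and NCE103, carbonic anhydrase, at 1.87 ± 0.08. The 10 lowest genes, from KTI12 at -4.62 ± 0.09 to RRT2 at -4.28 ± 0.20, all lay in a separate cluster of values near -4, where 103 and 153 genes lay at or below -3 on the 2 arrays. Among annotated genes outside that cluster, chosen after their values were seen, GPP2, a glycerol-3-phosphate phosphatase gene, had -2.83 ± 0.08, the transcription factor gene COM2 -2.59 ± 0.08 and ERO1, an oxidase of protein folding in the endoplasmic reticulum, -2.27 ± 0.11. In all, 3478 genes passed, 1476 higher and 2002 lower. The median gene lay at -0.11, and centring the arrays, which added 0.108 and 0.107, gave 3321 genes, 1743 higher and 1578 lower. Relative to that centre the list medians were 1.14 for ribosomal proteins, 1.08 for the respiratory chain, -0.50 for hexose transporters and -0.64 for chaperones. In the same contrast 74.0% of the 539 empty and 66.0% of the 144 Blank spots passed, and 161 (2 higher, 159 lower) of the genes that passed lay outside the control range. The 159 include genes of the cluster near -4, such as KTI12, and were not counted without them. A fit to the 2 arrays of this strain alone passed 1946 genes. That fit borrows no variance from the other strains, whose replicates differed less, and has fewer arrays.

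In the snq2 deletion strain, ribosome assembly, cell wall and chaperone genes fell under 089, while genes for the use of carbon sources other than glucose and for stress defence rose. Of the ribosome biogenesis genes, 51 of the 73 fell, 3 rose and 19 did not pass (52 and 4 when adjusted over the list alone). Their median was -0.94 (camera adjusted p = 9.73e-10, adjusted p = 0.385 with an estimated correlation). NOP58, a box C/D snoRNP protein, fell by 3.23 ± 0.13, the RNA helicase gene DBP2 by 3.49 ± 0.15, the RNA polymerase I gene RPA135 by 2.74 ± 0.12 and the nucleolar gene NSR1 by 2.00 ± 0.09. Of the cytosolic ribosomal proteins, 72 of the 136 fell, 7 rose and 57 did not pass (72 and 8 when adjusted over the list alone). Their median was -0.34 (camera adjusted p = 3.34e-06, adjusted p = 0.342 with an estimated correlation), with RPS28B at -2.04 ± 0.15 and RPS25A at -1.99 ± 0.13.

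Of the cell wall genes, 23 of the 36 fell, 5 rose and 8 did not pass (25 and 5 when adjusted over the list alone). Their median was -1.12 (camera adjusted p = 3.82e-05, adjusted p = 0.285 with an estimated correlation). FKS1, a catalytic subunit of glucan synthase, fell by 3.64 ± 0.10, and PIR3 and HSP150 by 2.83 ± 0.11 and 2.70 ± 0.12. SLT2, the MAP kinase of cell wall integrity, was among the 10 lowest genes at -3.37 ± 0.21. Of the heat shock and chaperone genes, 19 of the 26 fell, 2 rose and 5 did not pass, as when adjusted over the list alone. Their median was -0.89 (camera adjusted p = 9.95e-05, adjusted p = 0.285 with an estimated correlation). KAR2, the Hsp70 of the endoplasmic reticulum, fell by 2.13 ± 0.10, and the cytosolic chaperone genes SSE1 and SSA2 by 2.16 ± 0.10 and 1.68 ± 0.08.

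Of the glyoxylate cycle and gluconeogenesis genes, 17 of the 21 rose, 1 fell and 3 did not pass, as when adjusted over the list alone. Their median was 1.20 (camera adjusted p = 6.38e-06, adjusted p = 0.285 with an estimated correlation). ADY2 rose by 2.31 ± 0.11, the isocitrate lyase gene ICL1 by 1.82 ± 0.12 and MLS1 by 1.74 ± 0.11, while the malic enzyme gene MAE1 fell by 3.35 ± 0.18. Of the tricarboxylic acid cycle genes, 12 of the 20 rose, 1 fell and 7 did not pass, as when adjusted over the list alone. Their median was 0.47 (camera adjusted p = 9.91e-04, adjusted p = 0.285 with an estimated correlation), with SDH3 at 1.41 ± 0.09 and the isocitrate dehydrogenase gene IDH2 at -1.47 ± 0.09. Of the peroxisomal beta-oxidation genes, 13 of the 19 rose, 2 fell and 4 did not pass, as when adjusted over the list alone. Their median was 0.61 (camera adjusted p = 0.00294, adjusted p = 0.285 with an estimated correlation). CTA1, the peroxisomal catalase, rose by 2.05 ± 0.13 and PEX11, a gene of peroxisome division, by 1.63 ± 0.10.

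Of the general stress genes, 22 of the 31 rose, 5 fell and 4 did not pass, as when adjusted over the list alone. Their median was 0.76 (camera adjusted p = 4.65e-04, adjusted p = 0.399 with an estimated correlation). TMA10 and the small heat shock gene HSP26 rose by 3.48 ± 0.17 and 2.02 ± 0.09, while SSA4 and YGP1 fell by 2.07 ± 0.10 and 2.41 ± 0.12. Of the stationary phase genes, 16 of the 21 rose, 1 fell and 4 did not pass, as when adjusted over the list alone. Their median was 0.79 (camera adjusted p = 2.08e-05, adjusted p = 0.285 with an estimated correlation), with SPG4 at 2.04 ± 0.09. Of the proteasome genes, 15 of the 34 rose, 1 fell and 18 did not pass, as when adjusted over the list alone. Their median was 0.20 (camera adjusted p = 0.00405, adjusted p = 0.285 with an estimated correlation). Of the trehalose and glycogen genes, 11 of the 18 rose, 2 fell and 5 did not pass, as when adjusted over the list alone. Their median was 0.53 (camera adjusted p = 0.0375, adjusted p = 0.399 with an estimated correlation). That call was lost without replicate 2 of this strain (median 0.35, adjusted p = 0.0929, over a range of 0.00795 to 0.0929).

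Other high ratios in this strain were RGI2 at 3.39 ± 0.08, NCE103 at 2.96 ± 0.08, SIP18 at 2.93 ± 0.22, AZR1, a transporter of the major facilitator superfamily, at 2.60 ± 0.14, and CLN3, a G1 cyclin gene, at 2.49 ± 0.09. NOG1, a GTPase gene of large subunit assembly, was among the lowest at -3.31 ± 0.18. In all, 3276 genes passed, 1612 higher and 1664 lower, and 940 changed at least 2-fold. In the same contrast 32.3% of the 539 empty and 71.5% of the 144 Blank spots passed, and 333 (25 higher, 308 lower) of the genes that passed lay outside the control range. The count was 2105 without replicate 1 of this strain and 1672 without replicate 2.

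**Figure D2:**
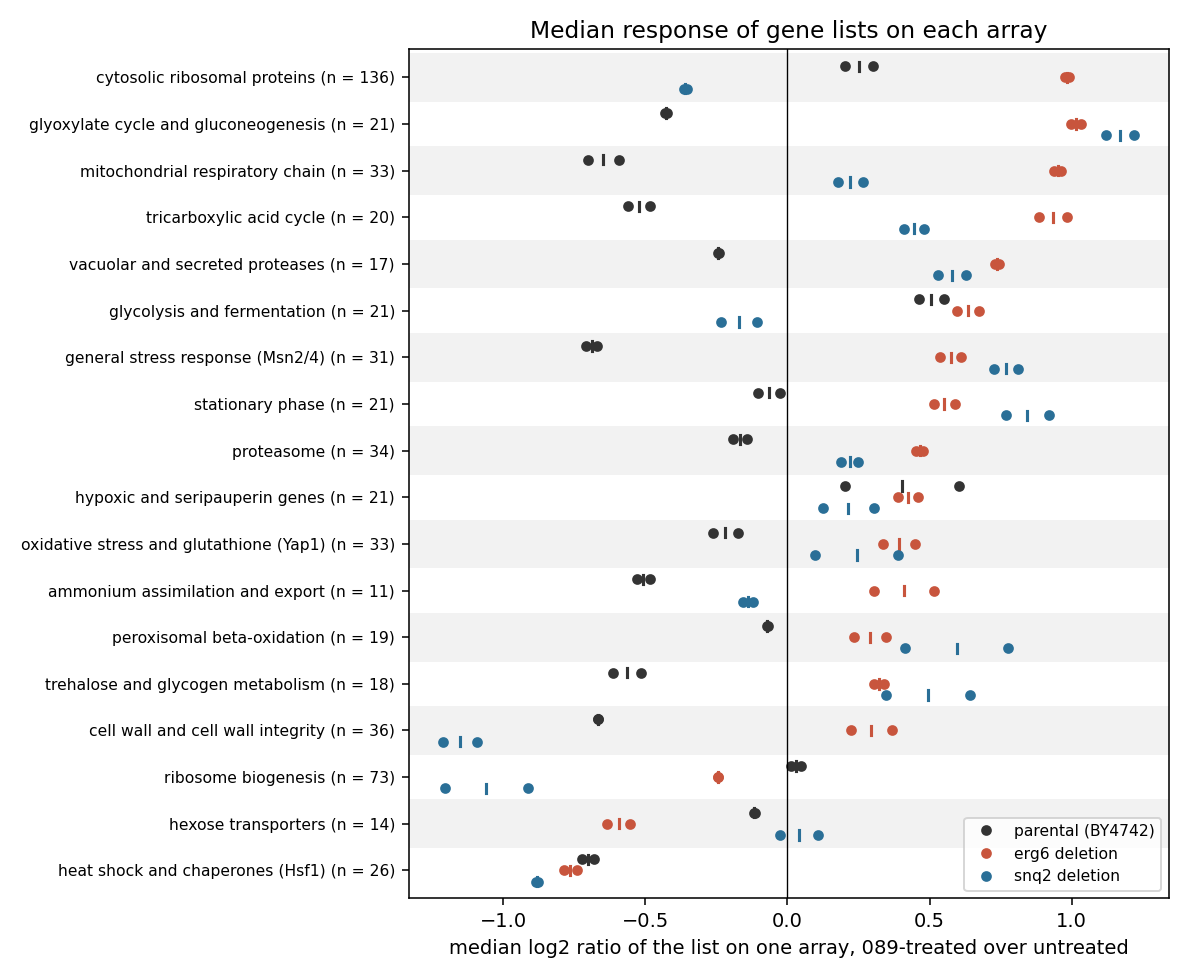
Median log2 ratio of treated over untreated (horizontal axis) of each gene list past the threshold in a strain or a difference between strains (vertical axis, with the number of genes). Each point is 1 of the 6 arrays and each tick the mean of the 2 arrays of a strain. The respiratory chain lies below 0 on both parental arrays and above 0 on the 4 arrays of the deletion strains, and heat shock and chaperone genes lie below 0 on all 6.

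Drug efflux and ergosterol genes, the groups to which the deleted genes belong, did not pass as lists in any contrast. Of the 28 efflux genes, the numbers that rose and fell were 8 and 9 in the parental, 5 and 9 in the erg6 deletion and 7 and 10 in the snq2 deletion strain, as when adjusted over the list alone. Their medians were -0.01, 0.04 and -0.13 (camera adjusted p = 0.948, 0.988 and 0.410). QDR2, with the smallest p of the list in the parental strain, rose there by 2.38 ± 0.08 and in the snq2 deletion strain by 1.47 ± 0.08. On the erg6 deletion arrays it had -0.43 and -0.46. In the parental strain QDR3 rose by 1.06 ± 0.12 and ICT1 fell by 1.13 ± 0.10. PDR12 fell by 3.24 ± 0.23 in the snq2 deletion strain. PDR5, the main ABC drug exporter beside SNQ2, fell by 2.40 ± 0.09 in the snq2 deletion strain, had 0.44 ± 0.09 in the erg6 deletion strain and did not pass in the parental strain at -0.17 ± 0.09. The snq2 deletion response minus the parental one was -2.24 ± 0.13 for PDR5. The call in the erg6 deletion strain was lost without replicate 1 of that strain (adjusted p = 0.0743) and in a fit to that strain alone (0.0748), over a range of 0.00574 to 0.0748. PDR1, which activates PDR5 and SNQ2, fell by 1.28 ± 0.10 in the parental and 1.81 ± 0.10 in the snq2 deletion strain. YOR1, another ABC exporter, had 0.30 ± 0.08 in the parental and -0.32 ± 0.08 in the erg6 deletion strain. The parental call was lost without parental replicate 1 or 2 (adjusted p = 0.176 and 0.155) and with quantile normalisation (0.0509), over a range of 0.0129 to 0.176. The erg6 deletion call was lost without either parental array (adjusted p = 0.0505 each), without erg6 deletion replicate 1 or 2 (adjusted p = 0.0695 and 0.110), in a fit to that strain alone (0.109) and with centred arrays (0.0775), over a range of 0.0204 to 0.110. PDR3 had -0.76 ± 0.09 in the erg6 deletion strain.

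Of the 28 ergosterol genes, 8 rose and 11 fell in the parental, 10 and 6 in the erg6 deletion and 4 and 10 in the snq2 deletion strain, as when adjusted over the list alone. Their medians were -0.11, 0.10 and -0.04 (camera adjusted p = 0.634, 0.330 and 0.337). ERG9 fell by 2.89 ± 0.11 in the parental strain and rose by 0.96 ± 0.11 in the erg6 deletion strain. ERG3, the C-5 sterol desaturase gene, rose by 0.98 ± 0.08 and 0.81 ± 0.08 in these strains and fell by 1.79 ± 0.08 in the snq2 deletion strain. ERG25, the C-4 methyl oxidase gene, rose by 1.34 ± 0.08 in the erg6 deletion strain.

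Averaged over the 3 strains, chaperone, cell wall and ribosome biogenesis genes fell and genes of the glyoxylate cycle, ribosomal proteins and stationary phase rose. Of the chaperone genes, 22 of the 26 fell, 2 rose and 2 did not pass, as when adjusted over the list alone. Their median was -0.69 (camera adjusted p = 3.46e-06, adjusted p = 0.345 with an estimated correlation), with SSA4 at -1.63 ± 0.06, STI1 at -1.64 ± 0.06 and YDJ1 at -1.57 ± 0.06. Of the cell wall genes, 24 of the 36 fell, 5 rose and 7 did not pass (25 and 6 when adjusted over the list alone). Their median was -0.56 (camera adjusted p = 0.00157, adjusted p = 0.345 with an estimated correlation), with PIR3 at -1.60 ± 0.06. Of the ribosome biogenesis genes, 48 of the 73 fell, 4 rose and 21 did not pass (51 and 6 when adjusted over the list alone). Their median was -0.41 (camera adjusted p = 9.86e-05, adjusted p = 0.579 with an estimated correlation).

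Of the glyoxylate cycle and gluconeogenesis genes, 13 of the 21 rose, 1 fell and 7 did not pass, as when adjusted over the list alone. Their median was 0.46 (camera adjusted p = 2.31e-04, adjusted p = 0.345 with an estimated correlation). Of the cytosolic ribosomal proteins, 76 of the 136 rose, 22 fell and 38 did not pass (77 and 23 when adjusted over the list alone). Their median was 0.24 (camera adjusted p = 9.87e-06, adjusted p = 0.345 with an estimated correlation). Of the stationary phase genes, 15 of the 21 rose, 2 fell and 4 did not pass (17 and 2 when adjusted over the list alone). Their median was 0.45 (camera adjusted p = 3.62e-04, adjusted p = 0.345 with an estimated correlation). Of the tricarboxylic acid cycle genes, 11 of the 20 rose, 2 fell and 7 did not pass, as when adjusted over the list alone. Their median was 0.24 (camera adjusted p = 0.00977, adjusted p = 0.345 with an estimated correlation). Of the histone and replication genes, 17 of the 31 rose, 3 fell and 11 did not pass, as when adjusted over the list alone. Their median was 0.25 (camera adjusted p = 0.0165, adjusted p = 0.345 with an estimated correlation). Of the peroxisomal beta-oxidation genes, 11 of the 19 rose, 2 fell and 6 did not pass (11 and 3 when adjusted over the list alone). Their median was 0.33 (camera adjusted p = 0.0439, adjusted p = 0.345 with an estimated correlation). The peroxisomal call was lost without snq2 deletion replicate 2 (adjusted p = 0.0635) and with the replicate block (adjusted p = 0.0506), over a range of 0.00302 to 0.0635.

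Of the 136 ribosomal protein genes, 63 rose and 26 fell in the parental, 109 rose and 3 fell in the erg6 deletion and 7 rose and 72 fell in the snq2 deletion strain, so that their average does not describe each strain. Nor does that of the cell wall genes, of which 15 rose and 6 fell in the erg6 deletion strain, or of the glyoxylate cycle and gluconeogenesis genes, of which 2 rose and 12 fell in the parental strain. Tricarboxylic acid cycle medians were -0.56 and -0.48 on the parental arrays, against 0.41 to 0.98 on the others. Ribosome biogenesis genes had 0.05 and 0.01 on the parental, -0.24 on both erg6 deletion and -0.91 and -1.20 on the snq2 deletion arrays. On the parental arrays the stationary phase list had -0.10 and -0.03 and the peroxisomal list -0.07 on both, with values above 0 on the others. SOL4 at 2.96 ± 0.49, ALE1 at 2.65 ± 0.13 and AI5_ALPHA at 2.19 ± 0.06 had the highest averages. The replicates of SOL4 differed widely, at 2.61 and 0.22 in the parental and 0.79 and 3.89 in the snq2 deletion strain. In the erg6 deletion strain they were 4.77 and 5.48. The standard errors and calls of the average rest on replicates within strains and leave out the spread between strains. AI5_ALPHA had 3.94 in the parental, 0.97 in the erg6 deletion and 1.65 in the snq2 deletion strain. YNR005C, RPA34 and RMA1 were lowest at -2.81 ± 0.29, -2.62 ± 0.07 and -2.55 ± 0.08, with values in the cluster near -4 on the erg6 deletion arrays. In all, 3972 genes passed, 1843 higher and 2129 lower. In the same contrast 72.4% of the 539 empty and 72.9% of the 144 Blank spots passed, and 172 (2 higher, 170 lower) of the genes that passed lay outside the central 95% of the control spots, -1.30 to 2.32. The 170 include genes of the cluster near -4, such as RPA34. A minimum of 1.5-fold left 1370 genes.

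Nuclear genes of respiration, the carbon cycles, stress defence, the cell wall and the ribosome had a higher response in the erg6 deletion strain than in the parental strain. Of the nuclear respiratory chain genes, 26 of the 33 were higher, 1 was lower and 6 did not pass, as when adjusted over the list alone. Their median was 1.80 (camera adjusted p = 1.57e-09, adjusted p = 0.195 with an estimated correlation). The difference was 3.37 ± 0.13 for ATP2, 2.46 ± 0.12 for RIP1 and 2.54 ± 0.13 for CYT1, the cytochrome c1 gene, and -3.30 ± 0.13 for QCR10. Of the respiratory genes of the mitochondrial genome, chosen after their values were seen, ATP8 at -4.47 ± 0.18, ATP6 at -3.76 ± 0.29, COX1 at -3.36 ± 0.25 and COX3 at -1.32 ± 0.14 went the other way, COX2 was higher at 0.49 ± 0.14, and COB at -0.39 ± 0.13 and OLI1 at 0.06 ± 0.13 did not pass. Of the tricarboxylic acid cycle genes, 16 of the 20 were higher, 2 were lower and 2 did not pass, as when adjusted over the list alone. Their median was 1.38 (camera adjusted p = 1.47e-05, adjusted p = 0.195 with an estimated correlation), with SDH3 at 3.35 ± 0.13. Of the glyoxylate cycle and gluconeogenesis genes, 16 of the 21 were higher, 1 was lower and 4 did not pass, as when adjusted over the list alone. Their median was 1.48 (camera adjusted p = 2.35e-05, adjusted p = 0.195 with an estimated correlation), with IDP2 at 2.80 ± 0.14 and MLS1 at 2.52 ± 0.16. Of the ammonium genes, 7 of the 11 were higher, 1 was lower and 3 did not pass (8 and 1 when adjusted over the list alone). Their median was 1.30 (camera adjusted p = 0.00505, adjusted p = 0.195 with an estimated correlation), with ADY2 at 2.23 ± 0.15.

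Of the general stress genes, 21 of the 31 were higher, 2 were lower and 8 did not pass (23 and 2 when adjusted over the list alone). Their median was 1.01 (camera adjusted p = 5.89e-06, adjusted p = 0.411 with an estimated correlation). CTT1, the cytosolic catalase, differed by 2.81 ± 0.15 and DDR2 by 2.75 ± 0.14. Of the cell wall genes, 20 of the 36 were higher, 4 were lower and 12 did not pass (21 and 4 when adjusted over the list alone). Their median was 0.71 (camera adjusted p = 1.55e-04, adjusted p = 0.195 with an estimated correlation), with YPS1 at 3.10 ± 0.19 and SED1 at 2.67 ± 0.15. Of the cytosolic ribosomal proteins, 89 of the 136 were higher, 15 were lower and 32 did not pass (91 and 16 when adjusted over the list alone). Their median was 0.73 (camera adjusted p = 1.47e-09, adjusted p = 0.195 with an estimated correlation), with RPL10 at 1.96 ± 0.11.

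The list medians of protein turnover, redox, reserve and stationary phase genes were higher in the erg6 deletion response as well, though many of their members did not pass. Of the proteasome genes, 20 of the 34 were higher, 6 were lower and 8 did not pass, as when adjusted over the list alone. Their median was 0.67 (camera adjusted p = 0.00139, adjusted p = 0.195 with an estimated correlation). Of the vacuolar and secreted protease genes, 10 of the 17 were higher, 3 were lower and 4 did not pass, as when adjusted over the list alone. Their median was 0.62 (camera adjusted p = 0.0187, adjusted p = 0.231 with an estimated correlation). Of the oxidative stress and glutathione genes, 17 of the 33 were higher, 4 were lower and 12 did not pass, as when adjusted over the list alone. Their median was 0.43 (camera adjusted p = 0.00566, adjusted p = 0.195 with an estimated correlation). Of the trehalose and glycogen genes, 11 of the 18 were higher, 2 were lower and 5 did not pass, as when adjusted over the list alone. Their median was 0.96 (camera adjusted p = 0.00895, adjusted p = 0.435 with an estimated correlation). Of the stationary phase genes, 11 of the 21 were higher, 1 was lower and 9 did not pass, as when adjusted over the list alone. Their median was 0.75 (camera adjusted p = 0.00705, adjusted p = 0.411 with an estimated correlation). Without erg6 deletion replicate 1 the stationary phase median was 0.49.

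Among single genes, ERG9 had the highest difference at 3.85 ± 0.16, followed by SOL4 at 3.71 ± 1.21, and by NCE102, an eisosome gene, at 3.47 ± 0.13. The SOL4 call was lost without erg6 deletion replicate 1 or 2 (adjusted p = 0.0580 and 0.101) and without parental replicate 2 (adjusted p = 0.185). It was also lost with quantile normalisation (adjusted p = 0.0543), the replicate block (0.0688), robust eBayes (0.0800) and array weights (0.0623), over a range of 0.0297 to 0.185. LSP1, another eisosome gene, differed by 3.23 ± 0.19, below ATP2 and SDH3. The glucokinase gene GLK1 differed by 3.06 ± 0.15. YOR029W was lowest at -5.11 ± 0.17. Among the other 9 lowest genes, KTI12, YJL120W, SVP26, YBR300C and YPL073C lay in the cluster near -4 on the erg6 deletion arrays. In all, 3615 genes passed, 1617 higher and 1998 lower, and 1922 differed at least 2-fold. In the same contrast 45.1% of the 539 empty and 69.4% of the 144 Blank spots passed, and 229 (6 higher, 223 lower) of the genes that passed lay outside the central 95% of the control spots, -2.21 to 3.19. The 223 include genes of the cluster near -4, such as KTI12.

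The response of the snq2 deletion strain also lay above the parental one for nuclear respiratory, carbon cycle and stress genes, and below it for ribosome assembly, ribosomal protein and glycolysis genes. Of the nuclear respiratory chain genes, 23 of the 33 were higher, 2 were lower and 8 did not pass (25 and 2 when adjusted over the list alone). Their median was 1.10 (camera adjusted p = 5.16e-09, adjusted p = 0.184 with an estimated correlation), with ATP2 at 1.96 ± 0.13. The mitochondrially encoded ATP8, ATP6, COX1, COX3 and OLI1, chosen after their values were seen, went the other way at -3.13 ± 0.18, -2.68 ± 0.29, -2.42 ± 0.25, -0.75 ± 0.14 and -0.61 ± 0.13, and COX2 at -0.03 ± 0.14 and COB at 0.15 ± 0.13 did not pass. Of the glyoxylate cycle and gluconeogenesis genes, 17 of the 21 were higher, 1 was lower and 3 did not pass, as when adjusted over the list alone. Their median was 1.77 (camera adjusted p = 3.06e-08, adjusted p = 0.184 with an estimated correlation), with MLS1 at 2.97 ± 0.16 and ALD4, a mitochondrial aldehyde dehydrogenase gene, at 2.97 ± 0.16. Of the tricarboxylic acid cycle genes, 13 of the 20 were higher, 0 were lower and 7 did not pass (15 and 1 when adjusted over the list alone). Their median was 1.07 (camera adjusted p = 4.47e-07, adjusted p = 0.184 with an estimated correlation). Of the general stress genes, 20 of the 31 were higher, 2 were lower and 9 did not pass, as when adjusted over the list alone. Their median was 1.32 (camera adjusted p = 3.27e-08, adjusted p = 0.271 with an estimated correlation), with HSP12 at 3.58 ± 0.20 and CTT1 at 3.00 ± 0.15.

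Of the ribosome biogenesis genes, 50 of the 73 were lower, 1 was higher and 22 did not pass (57 and 1 when adjusted over the list alone). Their median was -1.08 (camera adjusted p = 1.81e-10, adjusted p = 0.333 with an estimated correlation), with NOP58 at -3.36 ± 0.19 and RPA135 at -2.78 ± 0.17. Of the cytosolic ribosomal proteins, 73 of the 136 were lower, 4 were higher and 59 did not pass (83 and 5 when adjusted over the list alone). Their median was -0.60 (camera adjusted p = 3.06e-08, adjusted p = 0.253 with an estimated correlation), with RPL20A at -1.86 ± 0.14. Of the glycolysis and fermentation genes, 14 of the 21 were lower, 2 were higher and 5 did not pass (17 and 2 when adjusted over the list alone). Their median was -0.76 (camera adjusted p = 0.00174, adjusted p = 0.414 with an estimated correlation). The pyruvate decarboxylase gene PDC1 differed by -3.09 ± 0.12 and the enolase gene ENO2 by -1.65 ± 0.12, whereas GLK1 and the hexokinase gene HXK1 differed by 2.28 ± 0.15 and 2.27 ± 0.13.

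The list medians of reserve, stationary phase, peroxisomal, redox and protein turnover genes were higher in the snq2 deletion response, though many of their members did not pass. Of the trehalose and glycogen genes, 13 of the 18 were higher, 1 was lower and 4 did not pass, as when adjusted over the list alone. Their median was 1.07 (camera adjusted p = 5.52e-05, adjusted p = 0.271 with an estimated correlation). Of the stationary phase genes, 13 of the 21 were higher, 1 was lower and 7 did not pass (14 and 1 when adjusted over the list alone). Their median was 1.03 (camera adjusted p = 6.29e-06, adjusted p = 0.239 with an estimated correlation). Of the peroxisomal beta-oxidation genes, 10 of the 19 were higher, 2 were lower and 7 did not pass (11 and 2 when adjusted over the list alone). Their median was 0.61 (camera adjusted p = 7.14e-04, adjusted p = 0.217 with an estimated correlation). Of the proteasome genes, 17 of the 34 were higher, 1 was lower and 16 did not pass (20 and 1 when adjusted over the list alone). Their median was 0.47 (camera adjusted p = 1.42e-06, adjusted p = 0.184 with an estimated correlation). Of the oxidative stress and glutathione genes, 13 of the 33 were higher, 3 were lower and 17 did not pass (15 and 3 when adjusted over the list alone). Their median was 0.40 (camera adjusted p = 0.00130, adjusted p = 0.184 with an estimated correlation). Of the vacuolar and secreted protease genes, 7 of the 17 were higher, 3 were lower and 7 did not pass, as when adjusted over the list alone. Their median was 0.35 (camera adjusted p = 0.0490, adjusted p = 0.271 with an estimated correlation). The call of the vacuolar proteases was lost without parental replicate 1 (adjusted p = 0.0747), and without either erg6 deletion array or in a fit to the compared strains alone (adjusted p = 0.0716 each). It was also lost with centred arrays (0.0502), the replicate block (0.0565), array weights (0.0551), annotated genes only (0.0577) and without genes at the floor of the erg6 deletion arrays (0.0518), over a range of 0.00119 to 0.0747.

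Among single genes, TMA10 had the highest difference at 3.97 ± 0.24, followed by ERG9 at 3.63 ± 0.16. The histone gene HTB2 differed by 3.03 ± 0.13 and NCE103 by 3.12 ± 0.11. YEF3, translation elongation factor 3, had -3.28 ± 0.19, MAE1 -3.31 ± 0.25 and SKI3 -3.40 ± 0.26. In all, 2495 genes passed, 1042 higher and 1453 lower, and 1093 differed at least 2-fold. In the same contrast 8.53% of the 539 empty and 25.7% of the 144 Blank spots passed, and 330 (217 higher, 113 lower) of the genes that passed lay outside the central 95% of the control spots, -1.94 to 1.43. The count was 1202 and 1316 without parental replicates 1 and 2, and 1258 without snq2 deletion replicate 2.

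**Figure D3:**
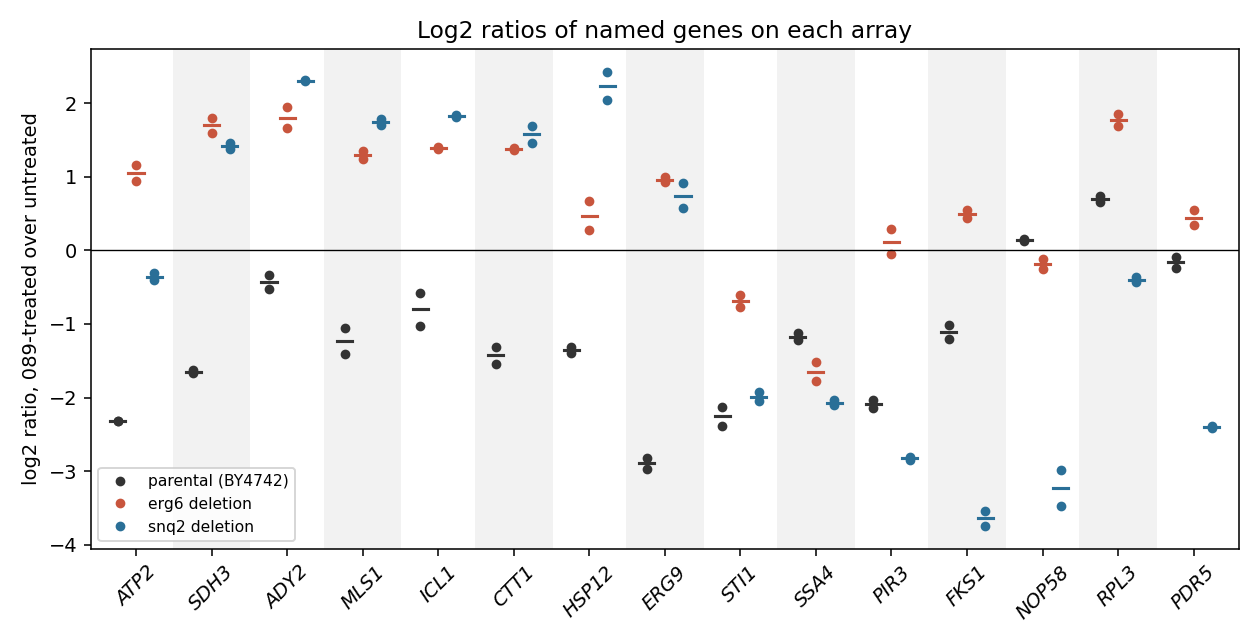
Log2 ratios of treated over untreated (vertical axis) of 15 genes (horizontal axis) on each of the 6 arrays. Points are arrays and ticks the mean of the 2 arrays of a strain. ATP2 has -2.32 in the parental and 1.05 in the erg6 deletion strain, and PDR5 has -2.40 in the snq2 deletion strain.

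Across genes, the parental and snq2 deletion responses correlated at r = 0.438 (rho = 0.453), the erg6 and snq2 deletion responses at r = 0.270 (rho = 0.203) and the parental and erg6 deletion responses at r = 0.031 (rho = -0.053). In the parental and snq2 deletion strains, 906 genes rose in both and 804 fell in both, against 440 and 444 for independent lists. In the parental and erg6 deletion strains these were 392 and 496, against 403 and 534, and in the 2 deletion strains 646 and 542, against 374 and 524. Over all 3 strains 218 genes rose and 290 fell in each, against 102 and 140 for independent lists, and 193 fell in the parental strain and rose in both deletion strains, against 99.8. The opposite pattern held for 48 genes, against 143. Without parental replicate 1 or 2 the parental and erg6 deletion counts became 210 and 220 or 255 and 268, and the count lower in both the parental and snq2 deletion strains became 455 or 474. The count higher in both of these was 589 without parental replicate 1. Without snq2 deletion replicate 1 or 2 the parental and snq2 deletion counts became 559 and 525 or 485 and 504, and without replicate 2 those of the 2 deletion strains 371 and 315. The arrays of different strains share no RNA but share the dye orientation, so an overlap above the number for independent lists is not free of dye effects. Blank spots, which carry no gene, correlated more strongly than genes for each pair of strains. Their r was 0.829 for the parental and snq2 deletion, 0.410 for the 2 deletion and 0.347 for the parental and erg6 deletion strains. Empty spots of single parental and snq2 deletion arrays correlated at 0.306 to 0.433, against 0.387 to 0.451 for genes. Such overlaps and correlations therefore do not by themselves show a shared response to the compound. With an estimated correlation, camera passed 0 of the 34 lists in each of the 6 contrasts. At an unadjusted p under 0.05 it passed 3 in the parental, 7 in the erg6 deletion and 5 in the snq2 deletion strain, 2 on average, 8 for the erg6 deletion difference and 7 for the snq2 deletion difference, and fry passed 22, 31, 30, 31, 20 and 28 in the same order.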

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

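The tests of strain differences reported in this part were planned before the data were examined, while the tests of explanations were all chosen after the results they bear on were seen.

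In the parental and erg6 deletion strains 1172 genes passed in opposite directions, 532 lower in the parental strain and 640 higher. Independent lists would give 394 and 546 opposite calls. Each of the 1172 also passed in the difference. That was fixed in advance, because the fit gives both strains the same standard error, so it adds no support. For the lists past the threshold in opposite directions in the 2 strains, the median difference was 1.80 for the respiratory chain, 1.48 for the glyoxylate cycle and gluconeogenesis, 1.01 for general stress and 0.71 for the cell wall. With an estimated correlation camera passed 0 lists in the parental strain, the erg6 deletion strain and their difference (lowest adjusted p = 0.343, 0.187 and 0.195), against 3, 7 and 8 at an unadjusted p under 0.05 and 22, 31 and 20 by fry. The call of the cell wall list in the erg6 deletion strain was lost without replicate 1 or 2 of that strain (adjusted p = 0.0625 and 0.0689, over a range of 0.00698 to 0.0689). Single genes with opposite calls and the largest differences were ERG9 (3.85), the eisosome genes NCE102 (3.47) and LSP1 (3.23), ATP2 (3.37), SDH3 (3.35), the mitochondrial outer membrane gene OM14 (3.13), the protease gene YPS1 (3.10), the glucokinase gene GLK1 (3.06) and YNL208W (2.98). Lower in the erg6 deletion strain were YOR029W (-5.11), YBR300C (-5.07), YLR235C (-5.05), KTI12 (-5.04), YJL120W (-5.00), YPL073C (-4.83) and SVP26 (-4.68).

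The parental and snq2 deletion strains gave 407 genes with opposite calls, 237 lower in the parental strain and 170 higher. These are fewer than the 430 and 454 opposite calls of independent lists. Each of the 407 also passed in the difference, which was again fixed in advance. The median difference was 1.77 for the glyoxylate cycle and gluconeogenesis, 1.07 for trehalose and glycogen, 1.32 for general stress and -0.60 for cytosolic ribosomal proteins. With an estimated correlation camera passed 0 lists in the snq2 deletion strain and in this difference as well (lowest adjusted p = 0.285 and 0.184), against 5 and 7 at an unadjusted p under 0.05 and 30 and 28 by fry. The call of the ribosomal list in the parental strain was lost without parental replicate 1 (adjusted p = 0.0956, over a range of 0.00665 to 0.0956), and that of the trehalose list in the snq2 deletion strain without its replicate 2 (adjusted p = 0.0929, over a range of 0.00795 to 0.0929). Single genes were ERG9 (3.63), HSP12 (3.58), PFS1 (3.53), OM14 (3.41), SDH3 (3.06) and the histone gene HTB2 (3.03), and in the other direction YOR309C (-3.67), YDR222W (-3.44) and the elongation factor gene YEF3 (-3.28). Differences at ERG9, OM14 and SDH3 were thus seen against both deletion strains, which share the same 2 parental arrays.

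Spots without a gene also passed the gene test. The percentages of empty and Blank spots that did so were 36.0 and 70.1 in the parental, 74.0 and 66.0 in the erg6 deletion and 32.3 and 71.5 in the snq2 deletion response. They were 72.4 and 72.9 for the average, 45.1 and 69.4 for the erg6 deletion difference and 8.53 and 25.7 for the snq2 deletion difference. A ratio past the threshold therefore does not by itself show a change of a transcript.

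The medians of the respiratory chain, glyoxylate cycle and general stress genes were below 0 in the parental strain, and their median differences from it were above 0 in both deletion strains. With an estimated correlation 0 of these list differences passed by camera, where 8 and 7 of all lists in the 2 differences passed at an unadjusted p under 0.05, and fry passed 20 and 28. Parental arrays turned in sign with otherwise like responses predict a negative correlation of the parental and snq2 deletion responses across genes. It was 0.438, with an SD of 0.0344 between array pairs, and 0.031 for the parental and erg6 deletion responses. Effects tied to the spot or dye would keep their sign on turned arrays. Blank spots correlated at 0.829 between the parental and snq2 deletion strains, so a positive value cannot exclude turned arrays. A shift or stretch of whole arrays would leave a difference near 0 after quantile normalisation. The medians of the respiratory chain differences were then 1.98 in the erg6 deletion and 1.23 in the snq2 deletion strain, and the lower of the 2 lower quartiles was 0.445, which argues against such a shift as the whole cause. A gene-specific dye effect of equal size in all strains cancels in these differences. A biological difference between the strains, such as an effect of 089 that depends on ERG6 or SNQ2, stays open, as do unlike growth states of the cultures, and neither was tested.

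On the erg6 deletion arrays, genes such as KTI12 and SVP26 lay in a cluster near -4. Of the 183 genes at or below -3 on either array, 88 lay above -2 on the other, which is 48.1% (95% confidence interval 40.7 to 55.6), so that for many of them single spots at the floor of a channel on one array are a candidate explanation. Among the 73 genes low on both arrays, 26, or 35.6%, were features without an annotated gene, against 8.11% of the other genes (Fisher's exact p = 6.36e-11). A lower RNA level in the treated cells as the only cause for that set predicts no such excess. For a single gene low on both arrays, a fall of its transcript stays open, as does a fault at its spot.

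The empty spots of the erg6 deletion arrays lay high, with a median of 2.11 and a lower quartile of 1.41, while the Blank spots had a median of -0.271. If a dye imbalance that lifts the empty spots were shared by weakly expressed genes, meiosis and sporulation genes, which are barely expressed in haploid cells, would lie as high. Their median over 26 genes was -0.278 (95% bootstrap limits over genes -0.54 and -0.10), below the lower quartile of the empty spots. These genes as a set thus did not share the lift of the empty spots. Without intensities it is not known whether their spots were as dim, so a dye imbalance at dim spots is not excluded. For the Blank spots such an imbalance stays open as well. The medians of the meiosis genes and of all genes (-0.11) both lie between the Blank quartiles of -0.78 and 0.72. Blank spots correlated at 0.829 between the parental and snq2 deletion strains, so an effect tied to the spot may be shared by the arrays of these 2 strains. Between the parental and erg6 deletion strains the correlation was 0.347, which such a shared effect as the whole source does not allow, since replicates within these strains reached 0.886 and 0.680. No biological explanation was tested for spots without a gene, and what they carry is not given in the sources used here.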

How the results depend on the processing

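The requirement to lie outside the control spots, the use of annotated genes alone and the removal of genes at or below -3 on either erg6 deletion array were chosen after seeing the data, and the other alternatives before the data were examined.

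Named genes and gene lists past the threshold kept their direction under the alternatives. For many named genes this was fixed in advance. Genes named for the highest or lowest values in a strain had both replicates on the same side, so leaving out an array could not turn them. The replicate block, robust eBayes and array weights can change the p-value but left estimates such as SOL4 in the erg6 deletion difference at 3.71. Kept directions in such checks do not show robustness. Of 6090 checks of named genes under the alternatives, 6017 kept direction and side of the threshold, 64 lost and 2 gained the call, and 7 turned in sign, each for a gene that did not pass. With each array left out in turn, so with fewer arrays, LEU2 ranged from -1.53 to 0.42 in the parental strain (higher than 0 without parental replicate 1) and from -1.40 to 0.56 in the erg6 deletion difference (higher than 0 without parental replicate 2). PDR3 in the parental strain ranged from -0.0517 to 0.0172 (turned without parental replicate 2), and on average YOR1 from -0.00572 to 0.0322 and SNQ2 from -0.0546 to 0.00907 (turned without snq2 deletion replicate 1 and 2). With centred arrays, which shifts all values of an array, PDR3 in the parental strain (0.00339) and SNQ2 on average (0.0273) turned. Of 1063 checks of gene lists that passed, 977 kept both and 86 lost the call, 67 of them with an estimated correlation. With that setting 0 lists passed in each of the 6 contrasts by camera, against 3, 7, 5, 2, 8 and 7 at an unadjusted p under 0.05 in the parental, erg6 deletion, snq2 deletion, average, erg6 deletion difference and snq2 deletion difference contrasts, and 22, 31, 30, 31, 20 and 28 by fry. Scaling of the arrays to one spread kept every call, direction, count, correlation and overlap compared within its limit. Quantile normalisation moved the correlation of the erg6 and snq2 deletion responses to 0.285, and the cause was not tested.

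With each array left out in turn, the genes past the threshold ranged from 1914 to 3829 in the parental strain, 1672 to 3656 in the snq2 deletion strain and 1202 to 2889 for its difference from parental. The correlations across genes ranged from 0.243 to 0.270 for the erg6 and snq2 deletion strains and 0.400 to 0.461 for the parental and snq2 deletion strains. The lowest counts came with an array of the compared strains left out, where fewer arrays remain, and the lone array of a strain is assumed to vary like the other strains. Of 60 checks of overlaps, 13 moved, all with a parental or snq2 deletion array left out. A fit to the compared strain alone, with fewer arrays for the variance, gave 1946 genes in the erg6 deletion strain.

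A minimum of 1.5-fold, which can only remove genes, left 2287, 2102, 2113 and 1370 genes in the parental, erg6 deletion and snq2 deletion strains and on average. Outside the central 95% of the control spots lay 240, 161, 333, 172, 229 and 330 genes in the order of the 6 contrasts given above. Without the 183 genes at the floor of the erg6 deletion arrays the correlation was -0.0354 for the parental and erg6 deletion strains, where it was 0.031 with all genes and so changed sign, and 0.256 for the erg6 and snq2 deletion strains. The estimated array weights were 1.39, 0.670 and 1.08 per array of the parental, erg6 deletion and snq2 deletion strains.

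With the replicate number as a block, 3251, 3306, 3103, 3826, 3468 and 2187 genes and 7, 15, 12, 8, 12 and 12 lists passed. The deviations of replicates correlated at 0.0948, -0.0423 and -0.00200 between strains, so the numbers gave no sign of pairing. No value was missing and no feature had more than 1 row, so a filter on missing values and separate probes gave nothing to compare. No pair of replicates correlated below -0.3, so the sign of no array was changed in the processing, and robust eBayes was not run for camera. Signal over background is not part of the deposited values, and its effect was not analysed here.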

Other observations

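The groups of mitochondrial features in this part were chosen after the results were seen, while the tests of gene lists were planned before the data were examined.

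In the parental strain several of the highest ratios were at features of the mitochondrial genome around COX1, ATP8 and ATP6, which are transcribed as one unit. The 9 features of this unit, COX1 with its intron frames, ATP8 and ATP6, had a mean of 3.16 (SD 1.10), and 9 of 9 rose, against 0.956 (SD 1.52) for the other 19 mitochondrial features. In the snq2 deletion strain the means were 1.04 and 0.0356, and in the erg6 deletion strain 0.180 and 0.0773. Outside the unit Q0010, Q0017, Q0032 and Q0092 also lay high in the parental strain at 3.25, 3.58, 3.93 and 3.85, while COX3 had 1.33, COX2 -0.45 and OLI1 -0.83. Intron frames overlap in sequence and are not independent features. A permutation test between the groups was tried and is not reported, because the unit was picked from the same parental values, and no explanation for these values was tested.

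Of the 34 gene lists, 15 did not pass in any contrast, among them drug efflux and ergosterol synthesis, which are described with the strains above. Counts of genes that rose and fell are given for the parental, erg6 deletion and snq2 deletion strains in turn, with the adjusted p of camera, and the other genes did not pass. Adjusted over the list alone, these counts differ by at most 2 genes. Of the 33 nitrogen catabolite repressed genes, 11 and 8, 9 and 9, and 9 and 14 rose and fell (medians 0.01, -0.17 and -0.16, adjusted p = 0.948, 0.961 and 0.482). Of the 55 amino acid biosynthesis genes, 14 and 18, 17 and 16, and 14 and 25 rose and fell (medians -0.04, 0.14 and -0.20, adjusted p = 0.948, 0.245 and 0.166). Of the 25 sulfur and methionine genes, 7 and 10, 3 and 9, and 4 and 11 rose and fell (medians -0.24, -0.31 and -0.25, adjusted p = 0.576, 0.259 and 0.137). Of the 20 amino acid permease genes, 4 and 4, 1 and 8, and 4 and 11 rose and fell (medians -0.12, -0.34 and -0.57, adjusted p = 0.798, 0.290 and 0.0504). Of the 19 unfolded protein response genes, 5 and 7, 3 and 5, and 3 and 6 rose and fell (medians -0.41, -0.17 and -0.32, adjusted p = 0.249, 0.775 and 0.246). Of the 24 autophagy genes, 6 and 5, 2 and 9, and 7 and 1 rose and fell (medians 0.00, -0.22 and 0.09, adjusted p = 0.948, 0.714 and 0.271). Of the 19 phosphate starvation genes, 4 and 10, 5 and 4, and 5 and 10 rose and fell (medians -0.36, -0.01 and -0.31, adjusted p = 0.145, 0.961 and 0.164). Of the 26 iron regulon genes, 7 and 6, 5 and 9, and 5 and 7 rose and fell (medians 0.11, -0.15 and -0.07, adjusted p = 0.864, 0.949 and 0.611). Of the 15 polyamine genes, 2 and 6, 1 and 3, and 2 and 7 rose and fell (medians -0.28, -0.06 and -0.49, adjusted p = 0.395, 0.729 and 0.147).

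Mating and meiosis genes did not pass as lists either. Of the 29 pheromone response and mating genes, 3 and 9, 5 and 11, and 5 and 5 rose and fell (medians -0.06, -0.31 and 0.06, adjusted p = 0.829, 0.479 and 0.933). Of the 7 genes specific to the other mating type a, 0 and 1, 1 and 3, and 1 and 1 rose and fell (medians -0.03, -0.31 and 0.24, adjusted p = 0.948, 0.412 and 0.915). Of the 4 genes specific to the strains' own mating type alpha, 0 and 1, 0 and 4, and 2 and 1 rose and fell (medians 0.03, -0.57 and 0.21, adjusted p = 0.948, 0.0755 and 0.487). Of the 26 meiosis and sporulation genes, 8 and 5, 3 and 13, and 6 and 5 rose and fell (medians 0.16, -0.28 and 0.01, adjusted p = 0.634, 0.232 and 0.915). On average over strains and in the erg6 deletion and snq2 deletion differences from parental the lowest adjusted p among the 15 lists was 0.109, 0.365 and 0.0667.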
